A study of Bos taurus with 6 samples.

How the data were processed

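Total RNA of 6 bovine embryonic stem cell lines was column-purified and made into stranded mRNA sequencing libraries, per the labels' protocols. One library was made per line. The lines carry the numbers 1, 3, 4, 6, 8 and 9 in the sample titles and are called lines here because the series' design text does so. The labels give all 6 the same cell line name and no second condition, so the samples form 1 group.

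The deposited table holds 1 column per line and 13994 genes, identified by Ensembl bovine gene IDs. As deposited, the values are on a log2 scale. The table is titled TPM, a unit in which reads are divided by gene length and scaled to a fixed total per library, and its values are those of log2(TPM + 1). The log base and the added 1 are not given in the sources used here and were read from the values, as the recovery of whole reads described below shows. Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the bovine genome build ARS-UCD1.2, also listed as bosTau9. The notes give no tool versions and no roles for the tools. After the log was undone, the listed genes summed to 607976 to 616432 TPM per line, or 61.2% ± 0.374 (SD, n = 6) of the total TPM of a library. The rest of each library was not analysed here.

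The gene names needed to read the table could not be attached. The files do not pair the IDs with names. The reference gene table, of the assembly named ARS-UCD2.0, holds 37063 genes, of which 0 have an Ensembl ID, and 0 of the 13994 IDs matched it. The planned work on 30 marker lists (pluripotency states, lineages, signalling, cell cycle and others), the 10 planned contrasts between lists, and the planned correlations between list scores were therefore not run, and no list gave a result. The planned rule for named genes named only genes with a symbol, so it named none. Instead 4 IDs are printed, the 2 genes with the largest gap above, and the 2 with the largest gap below, the nearest other line. They were chosen after their values were seen.

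Reads were recovered from the TPM values. For each gene, TPM is a whole number of reads divided by the gene's length and by 1 factor per line. The ratio of the factors between lines was taken from the most common ratio among low genes, and the smallest whole numbers that fitted a gene's 6 values were taken as its reads. All 13110 genes with any signal gave whole numbers in every line, with a largest deviation of 5.3e-09 against a tolerance of 1e-06. One further scale then made 98.5% of the gene lengths whole numbers of bases within 0.001 bases, and the other 201 genes needed a further whole factor. The recovered gene lengths had a median of 2387 bp. The TPM rebuilt from the recovered reads differed from the deposited values by at most 7.0e-14 of the value. A factor common to all 6 lines cannot be seen, so a recovered count is the smallest that fits. On simulated data for these genes, 99.2% of 10311 genes with at least 10 reads in every line were recovered exactly.

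The recovered reads over the listed genes numbered 12587023 to 17073260 per line, and this is the depth behind the listed genes only. For a gene of median length, 3 reads correspond to 0.106 to 0.144 TPM, which is the level that a count of 0 allows. Intervals and floors cover counting error only.

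A gene was called detected at a TPM of at least 1. Between-line variation was measured as the SD of log2(TPM + 1) over the 6 lines, among genes with a mean TPM of at least 5, with an SD above 1 counted as variable. A gene was called line-specific where 1 line lay at least 1 log2 unit above, or below, every other line. Line similarity was the correlation across genes of log2(TPM + 1). Variation beyond counting noise was tested per gene with Pearson's chi-square test on the recovered reads, among genes with at least 5 expected reads in every line, with median-of-ratios sizes and Benjamini-Hochberg adjustment at 0.05. That test was added after the table was seen. It compares these 6 libraries and not conditions, and no count model was fitted. With 1 library per line, a difference between lines has no replicate check: it joins the line, its culture and its library. The SD over lines is given as a description.

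The functions were tested on simulated data with 200 changed genes. The line-specific rule found 100% of 50 genes raised 4-fold in 1 line, 96.0% of 50 genes lowered 4-fold and 2.0% of 50 genes raised 2-fold, and it called 1 of 7997 unchanged genes. The chi-square test called 9 of 10851 unchanged genes. The simulated reads held counting noise only and no further spread between lines. These rates therefore do not apply to libraries that also differ in culture or preparation.

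The definitions of detection, variation and line-specificity were fixed before the data were examined. Of the 81 values under alternatives, 40 come from alternatives fixed then: other TPM minimums, a pseudocount of 0.1, median-of-ratios scaling, a larger gap, and leaving out each line for detected and variable genes. The other 41 come from alternatives added after the data were seen: removing the gene length trend, thinning the reads to equal totals, requiring 50 reads, and all alternatives for the chi-square test (20 expected reads, total reads as sizes, leaving out each line), for the coefficient of variation and for the gaps of the 4 printed genes. Scaling without the 100 most abundant genes was also added then. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.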

Results

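RNA of 6 bovine embryonic stem cell lines was profiled to examine their pluripotency. The lines are described by their makers as formative, a state between the naive pluripotency of the early epiblast and the primed pluripotency that precedes gastrulation. Each line gave 1 library. The values are TPM, a measure of a gene's share of the transcripts in a library that takes the gene's length into account. The 13994 listed genes carried 12587023 to 17073260 recovered reads per line. Because the genes are given by ID only, which pluripotency or lineage genes were expressed was not analysed here, and the comparisons concern how many genes the lines expressed, how alike the lines were, and how far single lines stood apart.

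The lines expressed nearly equal numbers of genes. Of the listed genes, 10049 ± 72.8 (SD, n = 6) reached a TPM of 1 in a line, from 9936 in line 9 to 10131 in line 4. In all 6 lines together, 9437 genes, or 67.4% of those listed, reached that level. A further 1250 genes reached it in some lines only. No read was found in any line for 884 genes. Between 1719 and 1828 genes were at 0 in a given line, which for a gene of median length allows a level of up to 0.106 to 0.144 TPM. Expression of the listed genes was spread over many of them: mean TPM was at least 10 for 6963 genes, at least 100 for 1253 genes and at least 1000 for 58 genes. The 10 most abundant listed genes made up 3.60% ± 0.188 of all transcripts (SD, n = 6), and the 100 most abundant made up 15.2% ± 0.491 (SD, n = 6). Both are shares of the whole library, of which the listed genes hold 61.2%, so their shares of the listed expression are larger. Genes not listed, which hold the rest of each library, may include more abundant ones. A TPM of at least 1 in one line and 0 in another was found for 205 genes, and a TPM of at least 5 in one line and 0 in another for 26. Among genes with a mean TPM of at least 5 there were 3 with a 0 in any line. None of these counts required a minimum of reads. The level that a 0 allows is higher for shorter genes, and a short gene can reach a TPM of 5 on a few reads. A 0 in such a gene therefore does not show that it was absent from the line.

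The lines were similar over the whole table. Across genes, which are not independent replicates, Pearson's correlation of log2(TPM + 1) had a median of 0.988 over the 15 pairs of lines. Lines 1 and 6 were the most alike, with a correlation of 0.993, and lines 4 and 8 the least, with 0.974. Spearman's rho ran from 0.970 to 0.989. Both measures took in all listed genes, including the 884 without a read in any line. Over genes with a mean TPM of at least 5, Pearson's correlation was lower, with a median of 0.972 and a lowest pair of 0.927. The median chi-square of a pair, over genes with at least 20 reads in the pair, ran from 2.09 for lines 1 and 6 to 11.9 for lines 4 and 8, against 0.455 for 2 samplings of one library. No 2 columns are thus samplings of one library, but whether the libraries come from separate cultures cannot be read from these values. Each line's mean correlation with the others ran from 0.981 in line 8 to 0.989 in line 1.

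The libraries differed by more than the counting error for 9898 of 11053 genes, or 89.6%, by the chi-square test at an adjusted p under 0.05. The test allows for counting error only and for no spread from culture or library preparation, so the count does not show that the lines themselves differ. Beyond counting noise, the median coefficient of variation between the libraries was 15.5%. Among the 3344 genes with a mean of at least 1000 reads, for which counting error matters least, it was 11.0%, with 4.41% at the 5th percentile and 30.8% at the 95th.

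A first principal component over the 8195 genes with a mean TPM of at least 5 set line 8, and less far line 3, against line 4. It held 47.3% of the variance between lines. The second component, with 28.2%, set line 9 against line 4.

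**Figure D1:**
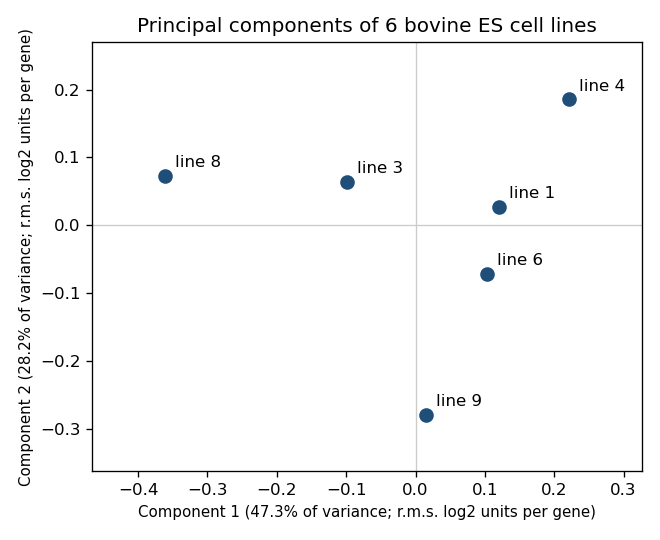
Each point is 1 library, that is 1 line, placed by the first (x axis) and second (y axis) principal components of log2(TPM + 1) over 8195 genes, in root-mean-square log2 units per gene. Line 8 lies alone at the left at -0.361, line 3 is between it and the rest at -0.099, and line 9 is lowest on the second component at -0.279.

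A small set of genes varied strongly. The SD of log2(TPM + 1) was above 1 for 52 genes, 0.635% of the 8195, while the median gene had an SD of 0.196. Line 8 was the lowest line for 26 of the 52 genes, where 8.67 would fall to each line if the lines were exchangeable. Without line 8 the number of variable genes was 34. Lines 3 and 8 were together the pair with the highest values for 15 of the 52 genes and the pair with the lowest values for 19, against 3.47 expected for any pair.

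Line-specific genes were concentrated in lines 8 and 4. Over all lines, 126 gene and line combinations lay at least 1 log2 unit from every other line, 53 above and 73 below. They comprised 120 genes, of which 6 were counted in 2 lines. Line 8 was lower than every other line for 44 genes and higher for 16. Line 4 was higher for 31 genes and lower for 9. Line 9 was lower for 11 genes (4 with median-of-ratios scaling) and higher for 1, and lines 1, 3 and 6 had 3 and 4, 2 and 4, and 0 and 1 such genes above and below. With exchangeable lines, 21 would fall to each line. Simulated libraries with counting noise alone held at most 7 such combinations over all lines.

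On the log2(TPM + 1) scale, the 31 genes higher in line 4 exceeded the mean of the other lines by a median of 1.44, with a range from 1.16 to 2.04. The 44 genes lower in line 8 differed from the mean of the other lines by a median of -2.12, with a range from -1.21 to -7.26, and for 9 of them the difference was at least 3 in size. The 9 genes lower in line 4 had a median difference of -2.19 and the 16 genes higher in line 8 one of 1.85. The few lower genes of lines 1, 3 and 6 had medians of -2.18, -2.15 and -2.03, and the 11 of line 9 one of -1.26. The value of line 6 rests on 1 gene with a mean of 6.83 reads. The scale understates the change of low genes. A gap of 2 log2 units to every other line was reached by 0 of the genes higher in line 4 and by 9 of the genes lower in line 8.

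**Figure D2:**
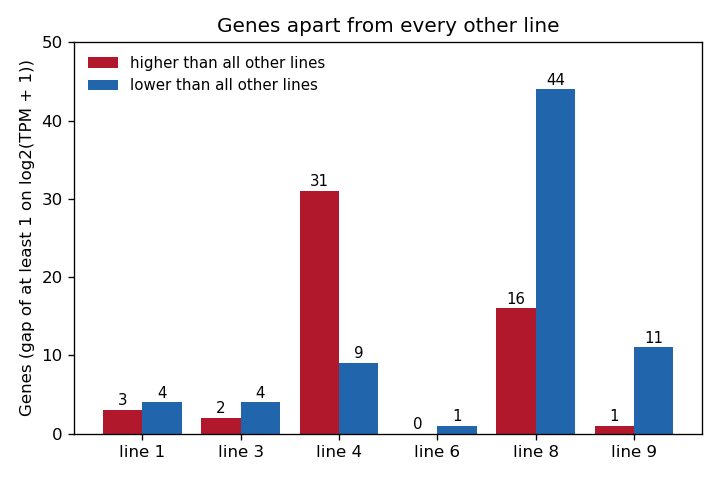
Bars give the number of genes (y axis) whose log2(TPM + 1) in a line (x axis) lay at least 1 unit above (red) or below (blue) all 5 other lines. Line 8 holds 44 lower genes and line 4 holds 31 higher genes, and line 6 holds 0 higher and 1 lower.

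The largest gaps below the other lines were near-absences in line 8 of genes that the other lines expressed strongly. ENSBTAG00000032875 had a TPM of 2.54 in line 8 (95% exact Poisson interval 1.53 to 3.97, from 19 reads) and 545 ± 70.5 in the other lines (SD, n = 5), which is 214-fold lower, with 2468 to 4202 reads in each of the others. ENSBTAG00000052306 had a TPM of 0.898 in line 8 (95% interval 0.464 to 1.57, from 12 reads) and 218 ± 61.0 in the other lines (SD, n = 5), which is 242-fold lower. The 2 genes farthest above the next-highest line lay 2.21 and 1.86 log2 units above it. By difference from the mean of the other lines, other genes lay further above, by up to 3.66 in line 8 and 3.22 in line 3. ENSBTAG00000001260 had a TPM of 34.3 in line 8 (95% interval 30.2 to 38.8) and 4.07 ± 1.61 in the others (SD, n = 5), an 8.43-fold difference. ENSBTAG00000049906 had a TPM of 80.6 in line 1 (95% interval 75.3 to 86.2) and 13.5 ± 5.30 in the others (SD, n = 5), a 5.98-fold difference. The genomic positions of these genes were not analysed here.

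Lines also differed by gene length. Across genes, the difference of line 9 from the other lines fell with gene length, with a Spearman correlation of -0.291. Its median difference was 0.06 on the log2 scale in the shortest of 5 bins of genes (median length 1086 bp) and -0.23 in the longest (median length 5165 bp). Lines 8 and 3 showed the opposite slope, with correlations of 0.145 and 0.141 and median differences of 0.12 and 0.07 in the bin of longest genes. Line 9 held the lowest value of the 6 lines for 30.7% of genes and line 8 the highest value for 31.7%, where 16.7% would fall to each line. Both shares depend on the scaling between lines: with median-of-ratios scaling line 9 was lowest for 23.6% of genes and line 8 for 25.7%, and line 8 was highest for 24.3% and line 9 for 25.3%.

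**Figure D3:**
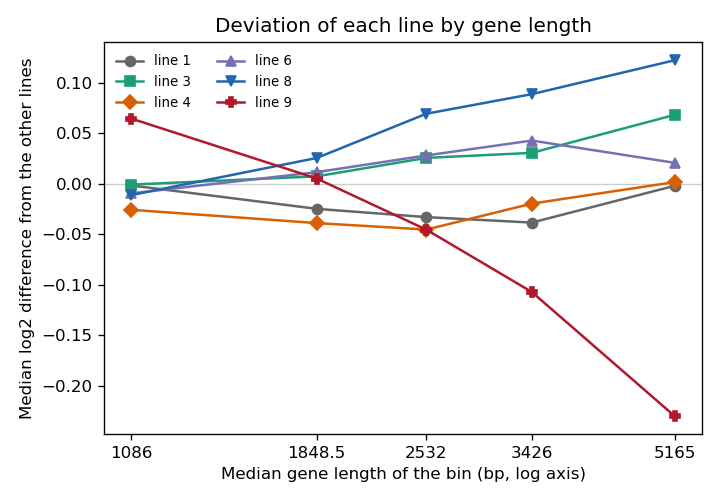
Points give the median log2 difference of a line from the mean of the other 5 lines (y axis) in 5 bins of gene length (x axis, median length in bp on a log axis), with 1 coloured line per cell line. Line 9 falls from 0.06 to -0.23 line 8 rises from -0.01 to 0.12 and line 3 reaches 0.07.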

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

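The tests of depth and of median-of-ratios scaling below were set out before their results were seen. Those of gene length were chosen after the length trend had been seen, and that of the 100 most abundant genes after the other results and the shares it rests on had been seen. The labels name no group among the 6 lines, so no biological explanation was tested for any pattern.

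Line 8 stood apart in the number of genes lower than in every other line. Its 44 genes lay far from the counts of the other lines, which ran from 1 to 11, and the gap made up 0.767 of the whole range, above Dixon's critical value for 6 samples. Of the 11 per-line measures checked, 1 passed, this one. Chance flags about 1 in 20 such groups, so with 11 checked a single pass has little weight. Line 8 was also the most deeply read line. The corrections were checked on its genes apart from all other lines, lower and higher together, which numbered 60. With every line thinned to 12587023 reads there were still at least 58 in each of 20 thinnings. With the gene length trend and the line's overall level removed the number was 64. With median-of-ratios scaling, which counters a few genes taking most of the counts, it was 60. The lower genes alone, 44 before, numbered 46 (median of 20 thinnings), 51 and 48 in that order. The higher genes, 16 before, numbered 16.5, 13 and 12. The shifts removed are small against a gap of 1 log2 unit: the median difference of line 8 in a length bin was at most 0.12 in size. Such corrections were unlikely to remove most of the genes, so they decide little. They show only that the number of both together stayed about as large. This held at equal depth, without a length trend of the whole line and under another scale factor. A difference between the lines themselves, in culture or in the library stays open, because each line has 1 library.

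Line 4 held the most genes higher than in every other line, 31. The number was at least 28 in each thinning, 41 with the length trend and the line's overall level removed, and 42 with median-of-ratios scaling. The median difference of line 4 in a length bin was at most 0.05 in size, small against a gap of 1. The number still rose with the trend removed and with the other scaling, so it is sensitive to small shifts between lines. The values show only that it stayed at 28 or more at equal depth. It also did not fall without a length trend of the whole line or under another scale factor. Whether the line or its library differs was not tested, because each line has 1 library.

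Line 9 held the lowest value for 30.7% of genes. Thinning left 30.6% and removing the length trend while keeping the line's overall level left 29.6%, both above every other line. With that level removed too, line 9 was lowest for 23.1% of genes, below the 25.6% of line 8. With median-of-ratios scaling the value was 23.6%, below the 25.7% of line 8. The share thus depends on the scaling, but this scaling recentres all genes of a line alike, so the fall does not show that a few genes took the counts. The 100 listed genes most abundant in each line held 16.0% of transcripts in line 9, against a mean of 15.2%. For the test, the 100 listed genes of highest mean TPM were left out and the lines scaled to equal sums over the others. Line 9 still held the lowest value for 28.8% of genes, against at most 22.2% in another line. This argues against the 100 genes left out as the whole cause. A shift of scale from other genes, listed or not, cannot be told apart from a shift of many genes, since both move a line's values alike. The length trend of line 9 does not depend on one scale factor and stays unexplained.

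Of the 4 genes printed by ID, 3 passed Dixon's critical value in TPM. The gap made up 0.865 of the range for ENSBTAG00000001260, 0.819 for ENSBTAG00000049906 and 0.699 for ENSBTAG00000032875. ENSBTAG00000052306 did not pass in TPM, because the other 5 lines spread from 157 to 302 TPM, although line 8 was at 0.898. These genes were picked for their gaps, so the flags are no independent evidence. Over all 8195 genes with a mean TPM of at least 5, 686 genes, or 8.37%, passed the same critical value on the log2(TPM + 1) scale. A gene can pass on one scale and not on the other, so that share is no base rate for the 4 genes. Among the 686 genes, the line apart was line 9 for 334, line 8 for 178 and line 4 for 129. This split was not repeated with median-of-ratios scaling. With that scaling the line-specific genes lower in line 9 fell from 11 to 4, so the lead of line 9 may depend on the scaling.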

How the results depend on the processing

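Of 81 values under alternatives, 65 stayed near the reported ones (counts and the CV within 1.5 times, correlations within 1 SD of the 15 pairs, gaps at least 1). Counts and the CV have no direction that could reverse. Which line was most often lowest or highest is not among the 81, and it changed with median-of-ratios scaling. The cause of the other changes was not tested, except where fewer genes or a stricter rule set it. The median correlation of 0.988 was 0.972 over genes with a mean TPM of at least 5 and 0.982 with a pseudocount of 0.1; the lowest pair was 0.927 in the first and the highest 0.986 in the second. The 52 variable genes became 89 with a minimum mean TPM of 1 and 91 with none, and 34 to 63 with each line left out, the lowest without line 8. The 126 line-specific gene and line combinations became 196 with a minimum of 1 and 14 with a gap of 2. With the minimum of 1, the genes higher in line 4 numbered 53 and in line 8 34; with the gap of 2 they were 0 and 1, and those lower in line 8 and line 9 were 9 and 1. With median-of-ratios scaling, 4 genes were lower in line 9, against 11. The alternatives for marker lists and list correlations were not run, since no ID had a name. No paired analysis was possible because there is only 1 group. Depth limits calls near 3 reads: 47 of the variable genes had a mean of at least 50 reads.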

Other observations

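The genes in which line 8 stood apart were often those in which line 3 came next. Of the 44 genes lower in line 8 than in every other line, line 3 was the next lowest for 23, where 8.8 would fall to each of the other lines if they were exchangeable. Of the 16 genes higher in line 8, line 3 was the next highest for 10, against 3.2. Genes are not independent, so these counts carry no test. This was noticed after the data were examined.

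The 44 genes lower in line 8 had a median length of 1647 bp, and the 31 genes higher in line 4 had a median length of 2356 bp. The median of the 8195 genes among which these were called was 2532 bp. The 11 genes lower in line 9 had a median length of 2974 bp.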
